A study of Mus musculus with 6 samples.

How the data were processed

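Total RNA of 6 mouse embryonic fibroblast samples, 3 with truncated and 3 with full-length NELF-B, was amplified, labelled with biotin and hybridised to single-colour Illumina bead arrays, per the labels. The groups and replicate numbers were taken from the sample titles. The deposited table of the whole series gives, per the file headers, an average signal intensity and a detection p-value for each of 25697 probes on each array and calls itself non-normalized. The submitters' processing notes name GenomeStudio, with no version or settings. The deposited intensities held no background subtraction, since the lowest was 103. The deposited detection p-values run in steps of 1 in 798, taken here as the number of negative controls. A second deposited table, the series matrix, holds intensities on a linear scale whose sorted values agree within 0.1% for over 98% of probes on every array, so they look quantile normalized, which no label states. The median of each of its columns was 143, its direction and scale follow the intensities, and each column correlated best with the same sample's intensities (r of 0.9996 or more). That table was used only as an alternative. No column of values was left unused (0 columns). No genome build applies, and no coordinates are given. Chip and scan date are not given in the sources used here, so chip could not be fitted as a block.

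Probes were named through their RefSeq accession against the gene table of assembly GRCm38.p6. Of 25697 probes, 24202 matched by accession, 536 by current symbol and 297 by a unique synonym, and 661 kept the symbol of the file. The file's symbols had been turned into dates or numbers for 32 probes, of which 31 were named by accession and 1 stayed unnamed. The file's symbol Nelf belongs to Nsmf and not to the NELF complex.

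Intensities were processed with limma 3.58.1 in R 4.3.3. Background was corrected by normexp with the negative controls' mean and spread inferred from the detection p-values (neqc), an offset of 16 was added, and values were quantile normalized and put on the log2 scale, so fold changes of dim probes are understated. Probes with a detection p under 0.05 on at least 3 of the 6 arrays were kept (12227 probes), and each gene was stood for by its probe with the highest mean over all arrays, which left 8990 genes. For 2347 genes more than 1 probe passed. Among the 144 called genes, 36 had more than 1 tested probe, and in 4 (Synm, Asph, Ccn1 and Sort1) a probe had the opposite sign. The groups were compared with lmFit and eBayes on 2 group means, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. A gene was counted as shown to differ by less than 2-fold, in the normalized values, where its 95% confidence interval lay within 1 log2 unit either way. A probe not above background on any array of a form has only a bound, computed against the lowest signal above background on each array.

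Before the data were examined, 34 gene lists with 1090 genes were fixed from textbook knowledge, and so were the comparisons, the alternatives and the rule for naming genes. The 27 lists with at least 5 measured members were tested with camera at its preset correlation of 0.01 (two-sided, Benjamini-Hochberg over the 27 lists), and again with an estimated correlation and with fry. Named genes are the NELF subunits, the 12 genes with the largest change in each direction among those past the threshold with no overlap between the arrays of the forms (placeholder symbols left out), up to 4 members of each list with the smallest p, and the sex-linked genes. Thbs2, Dcn, Ogn, Mcm3 and Chac1 were added after their values were seen, because they complete a count of called list members. Exact permutation tests were two-sided, and 0.1 is the smallest p they allow for 3 against 3 arrays.

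The fit was tested on 20 simulated data sets of 8990 genes with the real means and the estimated spread, in which 200 genes changed. It recovered 36.0% of genes changed 1.5-fold, 89.0% of those changed 2-fold and 98.9% of those changed 3-fold, 4.8% of its calls were false, and the 95% intervals covered 94.9% of the true values. These simulated genes vary independently, which real genes do not. Their variances were drawn from the fit's own model, so the share of false calls and the coverage were bound to lie near 5% and 95%. On the real data a variance trend with robust eBayes changed the count from 144 to 728, so the real spread may depart from that model. The alternatives changed the background correction, the normalization, the filter on dim probes, the probes per gene, the variance model, array weights, the block and the arrays used. No 2 arrays held identical values. Figures were drawn with matplotlib 3.10.9.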

Results

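The series profiled mouse embryonic fibroblasts (MEFs, connective tissue cells grown from mouse embryos) that carried 1 of 2 forms of NELF-B, a subunit of the negative elongation factor complex, which holds RNA polymerase II near promoters. One form was the full-length protein, and the other a truncated protein that the labels tie to an ATG start codon. The series is about NELF-B translation that starts at a codon other than AUG. Total RNA was hybridised to Illumina mouse bead arrays with 25697 probes, 3 arrays per form. All cells were of the C57BL/6 background and were harvested at 50% confluence in medium with 10% serum. The median intensity per array was 143 to 152, and 46.4% to 48.7% of the probes were above background. The number of arrays, 3 per form, limits the precision. Nothing in the labels says whether the 3 samples of a form were separate cultures, so the p-values measure the spread between these samples, which may be technical. The comparison asks how far the transcriptome differs between cells with the short and the long protein. Log2 fold changes are truncated over full-length, with the standard error (SE) from limma and n = 3 arrays per form throughout.

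None of the transcripts of the 4 NELF subunits passed the test between the forms. The Nelfb probe with the higher signal read 7.01 ± 0.08 (SD, n = 3) on the log2 scale with the truncated form and 6.69 ± 0.09 (SD, n = 3) with the full-length form, a log2 fold change of 0.32 ± 0.11 (adjusted p = 0.144, limma). All 3 truncated arrays lay above all 3 full-length arrays, and the two-sided exact permutation p was 0.1, the smallest that 3 against 3 arrays can give. The other Nelfb probe was dimmer and gave a log2 fold change of -0.04 ± 0.18 in a fit of every probe. The files do not give the probes' place in the transcript, so these values do not check which form a sample carried. Nelfa had a log2 fold change of 0.11 ± 0.12, Nelfcd of 0.21 ± 0.12 and Nelfe of 0.04 ± 0.12, with adjusted p from 0.369 to 0.887.

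The 2 sets of cells had similar expression profiles. Of 8990 genes tested, 8733 (97.1%) had a 95% confidence interval wholly within 2-fold either way, and 6287 (69.9%) within 1.5-fold. Because folds of dim probes are understated, for dim genes the interval bounds the measured fold and not the difference in RNA. The correlation across genes was 0.992 on average between arrays of one form and 0.988 between arrays of different forms. With limma and Benjamini-Hochberg adjustment, 144 genes (1.6%) differed at an adjusted p under 0.05, of which 46 were higher and 98 lower with truncated NELF-B. Of these, 29 differed at least 2-fold, 2 higher and 27 lower. Only Lcn2, Igfbp2 and Anpep had an interval wholly beyond 2-fold. Without an adjustment, 1808 genes (20.1%) had p under 0.05, nearly evenly split into 879 higher and 929 lower. The arrays of the forms did not overlap for 25.7% of the genes, where chance gives 10%. The number of called genes depended on single arrays. It was 0 without truncated replicate 1, full-length replicate 1 or full-length replicate 2, 6 without full-length replicate 3, 11 without truncated replicate 2 and 304 without truncated replicate 3. In the 3 refits with a count of 0, 1178, 1429 and 1543 genes had an unadjusted p under 0.05. It also depended on the background correction and on the normalization, though cyclic loess in place of quantile gave 156 genes, 143 of them among the 144. With no background correction 706 genes were called, 52.5% of them lower, and with median scaling in place of quantile 81 genes, 85.2% of them lower, against 68.1% lower among the 144.

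**Figure D1:**
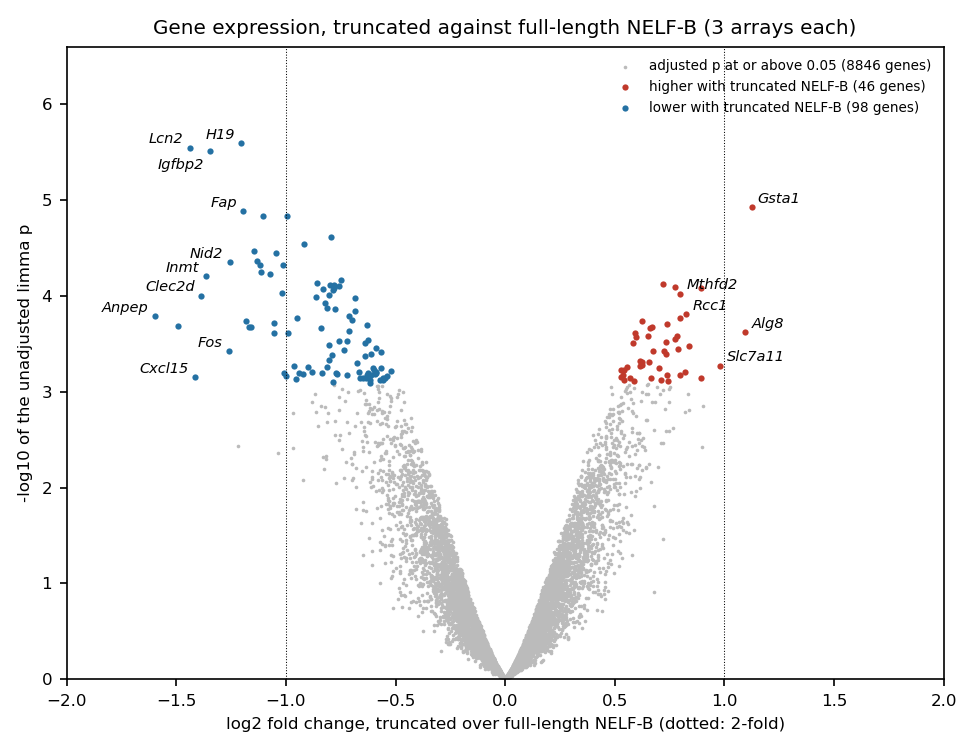
Each point is 1 of 8990 genes, with the log2 fold change of truncated over full-length NELF-B on the x axis and -log10 of the unadjusted limma p on the y axis (n = 3 arrays per form). Red marks the 46 genes higher and blue the 98 genes lower with the truncated form at an adjusted p under 0.05, and dotted lines mark 2-fold.

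The largest decrease among the genes lower with truncated NELF-B was that of Anpep, the cell surface peptidase aminopeptidase N, at 3.03-fold (log2 fold change -1.60 ± 0.26). Its probe was above background on 2 of the 3 truncated arrays. Lcn2, an iron-siderophore binding acute-phase protein, was 2.71-fold lower (-1.44 ± 0.14, adjusted p = 0.0091), and Igfbp2, an insulin-like growth factor binding protein, 2.54-fold lower (-1.35 ± 0.13, adjusted p = 0.0091). H19, an imprinted noncoding RNA, was 2.30-fold lower (-1.20 ± 0.11, adjusted p = 0.0091). The chemokine Cxcl15 (-1.42 ± 0.28), the lectin-like receptor ligand Clec2d (-1.39 ± 0.21), the methyltransferase Inmt (-1.37 ± 0.19) and the immediate early transcription factor Fos (-1.26 ± 0.23) also fell. So did the basement membrane gene Nid2 (-1.26 ± 0.17), the alcohol dehydrogenase Adh1 (-1.18 ± 0.19) and the complement protease gene C1s1 (-1.17 ± 0.19). The Adh1 probe was above background on 1 of the 3 truncated arrays. The other C1s1 probe gave a log2 fold change of -0.56 on the 6 arrays. Fap, a fibroblast surface protease, was not above background on any truncated array and on all 3 full-length arrays, which makes it at least 1.75-fold lower (adjusted p = 0.0189). That bound is the mean of the brighter group over the lowest signal above background on each dimmer array.

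The largest increases with truncated NELF-B were smaller than the largest decreases. Gsta1, a glutathione S-transferase with close paralogs that its probe could also read, was 2.18-fold higher (1.12 ± 0.13, adjusted p = 0.0189) and above background on 1 of the 3 full-length arrays. Alg8, a glucosyltransferase of protein N-glycosylation, was 2.14-fold higher (1.09 ± 0.19), and the cystine transporter gene Slc7a11 1.97-fold higher (0.98 ± 0.19), the latter above background on 2 of the 3 full-length arrays. Rcc1, the nucleotide exchange factor of Ran, rose by 0.82 ± 0.13, and Mthfd2, a mitochondrial enzyme of one-carbon metabolism, by 0.80 ± 0.12. The repair gene Xrcc2 rose by 0.80 ± 0.16. Ifrd2 (0.89 ± 0.18), Zfp367 (0.84 ± 0.15, above background on 2 of the 3 full-length arrays), Sac3d1 (0.79 ± 0.14) and Npm3-ps1 (0.90 ± 0.13), named as a pseudogene of Npm3 with which it may share its signal, were also higher. Zfp382 and Sprr2k, the second a member of a family of near-identical genes, were above background only with the truncated form, at least 1.43-fold (adjusted p = 0.0346) and at least 1.26-fold higher (adjusted p = 0.0487). For dim genes these sizes depended on the background correction. With none, Gsta1 changed by 0.33, Slc7a11 by 0.33, Anpep by -0.61 and Adh1 by -0.36, all with the same direction.

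**Figure D2:**
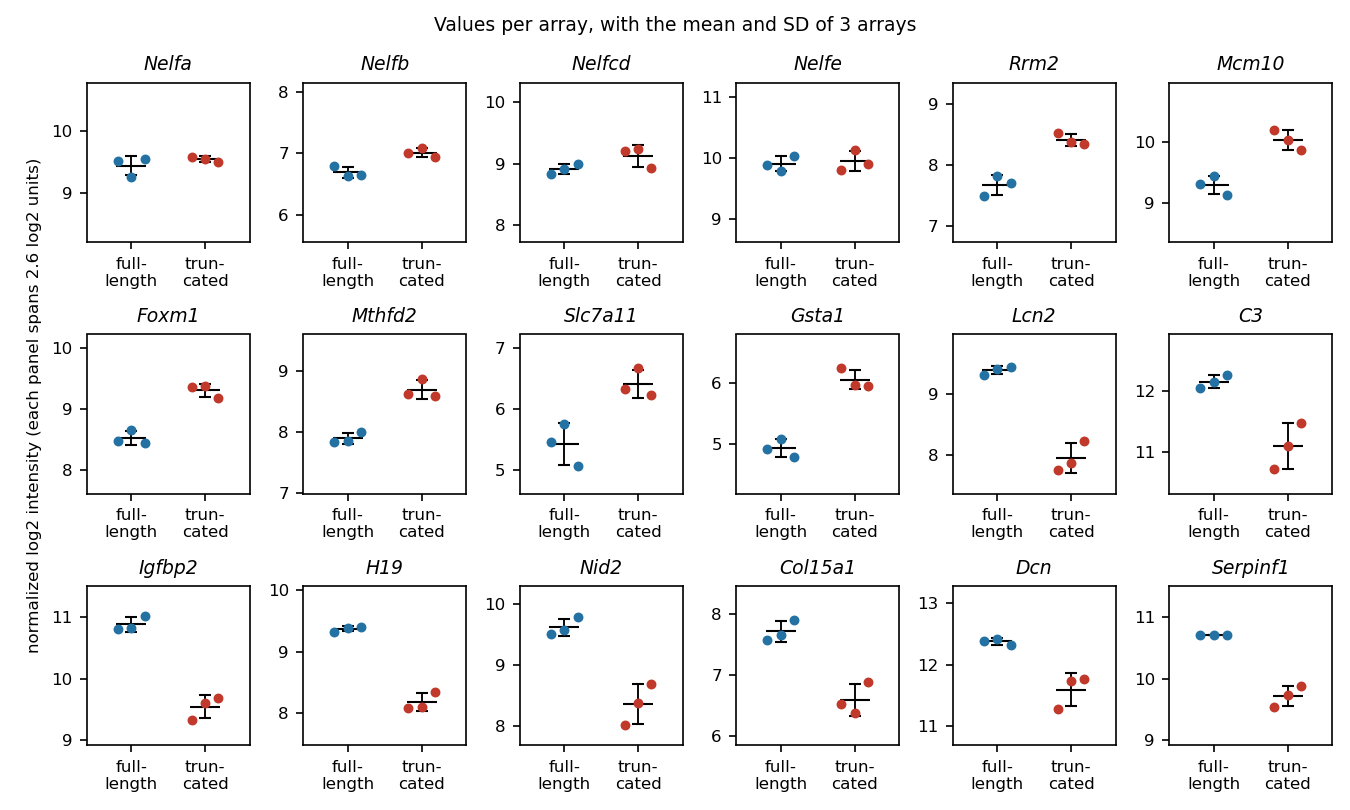
Normalized log2 intensity on the y axis for 18 genes, 1 panel each, with full-length arrays in blue and truncated arrays in red, and the mean and SD (n = 3) in black. Each panel spans the same number of log2 units, and the 4 NELF subunits shift by at most 0.32 where Lcn2 shifts by -1.44.

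The lists of DNA replication and of mitosis genes shifted higher with truncated NELF-B by camera with its preset correlation (adjusted p = 3.8e-16 and 2.1e-11). With an estimated correlation, neither passed (adjusted p = 0.287 and 0.311). Of 34 measured S phase and DNA replication genes, 5 rose at an adjusted p under 0.05 over all genes and 29 did not pass, while 26 rose when adjusted over the list alone. The values were above 0 for 33 of the 34, with a median log2 fold change of 0.49. Pola2, a subunit of DNA polymerase alpha, rose by 0.72 ± 0.10, the ribonucleotide reductase subunit gene Rrm2 by 0.74 ± 0.12, the replication factor Mcm10 by 0.74 ± 0.13, the helicase subunit gene Mcm3 by 0.74 ± 0.15 and the flap endonuclease Fen1 by 0.58 ± 0.10. Of 28 G2/M and mitosis genes, all had values above 0, with a median of 0.41. Foxm1, a transcription factor of mitotic genes, rose by 0.77 ± 0.11, and 18 of the 28 rose when adjusted over the list alone. Mad2l1 (0.46 ± 0.11), Plk1 (0.44 ± 0.11) and Cdc20 (0.46 ± 0.11) did not pass over all genes. Truncated replicate 3 lay nearest to the full-length arrays. The mean of the replication list, centred on all arrays, was 0.32, 0.27 and 0.10 on truncated replicates 1, 2 and 3, and from -0.33 to -0.15 on the full-length arrays.

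The structural matrix list shifted lower with truncated NELF-B, with a median of -0.40 (camera adjusted p = 1.1e-10 with the preset correlation, adjusted p = 0.287 with an estimated correlation). Of 36 measured collagens and structural matrix genes, 7 fell and 29 did not pass, and when adjusted over the list alone 17 fell and 1 rose. Besides Nid2, these were Col15a1, a basement membrane collagen (-1.12 ± 0.16), Spon2 (-0.92 ± 0.12), the microfibril gene Mfap2 (-0.83 ± 0.12), Thbs2 (-0.77 ± 0.12) and the small proteoglycans Dcn (-0.79 ± 0.14) and Ogn (-0.81 ± 0.15). Of 21 matrix proteases and inhibitors, Serpinf1, a secreted serpin (adjusted p = 0.0189), and the stromelysin Mmp3 (-0.71 ± 0.11) fell, 8 fell when adjusted over the list alone, and the median was -0.31 (camera adjusted p = 6.2e-06, adjusted p = 0.287 with an estimated correlation). Adamts4 (-0.57 ± 0.13) and Htra1 (-0.41 ± 0.10) did not pass. Of 20 collagen processing genes none passed over all genes, 6 fell when adjusted over the list alone, and the median was -0.20 (camera adjusted p = 7.0e-04, adjusted p = 0.379 with an estimated correlation), with Adamts2 at -0.55 ± 0.12 and P4ha1 at -0.86 ± 0.20. On truncated replicate 3 the centred mean of the structural matrix list was -0.06, against -0.26 on the other truncated arrays and 0.15 to 0.22 on the full-length arrays.

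Of 35 fibroblast identity and growth factor genes, Fap, the growth factor Ptn (-0.76 ± 0.13) and the secreted matricellular gene Ccn5 (-0.59 ± 0.12) fell, and when adjusted over the list alone 6 fell and 3 rose. The median was -0.14 (camera adjusted p = 0.0167, adjusted p = 0.287 with an estimated correlation). That list did not pass without full-length replicate 2 (adjusted p = 0.118), with a range of 0.0029 to 0.118 over 16 alternative fits. Zeb2 (-0.74 ± 0.15) did not pass. No member of the 24 myofibroblast and SRF contractile genes passed over all genes, and when adjusted over the list alone 3 fell and 1 rose, with Mylk at -0.62 ± 0.14, Actg2 at -0.42 ± 0.11, Fhl1 at -0.41 ± 0.11 and Ankrd1 at 0.51 ± 0.13. That list's median was -0.16 with a camera adjusted p of 0.0493, and of 0.287 with an estimated correlation. It passed in 5 of 16 alternative fits, with adjusted p from 0.0113 to 0.223. Without truncated replicate 3, full-length replicate 1 or full-length replicate 2 its adjusted p was 0.20, 0.106 and 0.223.

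Few genes of the NF-kB and interferon lists passed, and both lists shifted lower by camera with the preset correlation but not with an estimated one (adjusted p = 0.366 and 0.379). Of 30 NF-kB targets and chemokines, Lcn2, the complement component C3 (-1.05 ± 0.18) and the chemokine Cxcl16 (-0.77 ± 0.15) fell and 27 did not pass. The acute-phase gene Saa3 stood at -0.84 ± 0.18 (adjusted p = 0.0613). Values were below 0 for 20 of the 30, 7 fell when adjusted over the list alone, and the list's median was -0.11 (camera adjusted p = 0.0079). Of 35 type I interferon response genes, 31 had values below 0, and Bst2, which tethers budding virus to the cell (-1.06 ± 0.17), was the only one that fell over all genes, while 2 fell when adjusted over the list alone. Ifit3 (-0.60 ± 0.13), Igtp (-0.69 ± 0.20) and Mx2 (-0.53 ± 0.18) did not pass. The interferon list's median was -0.31 and its mean -0.30 (camera adjusted p = 1.0e-06), and with fry it did not pass (adjusted p = 0.180). Its mean was -0.19 without truncated replicate 1. The centred mean of the interferon list was -0.38, -0.16 and 0.08 on truncated replicates 1, 2 and 3 and 0.09 to 0.19 on the full-length arrays, so that truncated replicate 3 lay at the full-length level.

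The unfolded protein response and ATF4 target list shifted higher with truncated NELF-B, with a median of 0.22 (camera adjusted p = 7.1e-06, adjusted p = 0.146 with an estimated correlation). Its estimated correlation was -0.026, below the preset, so a higher correlation does not account for that loss. The same holds for the fibroblast identity list (estimated correlation 0.0083) and the myofibroblast list (-0.0049), both below the preset of 0.01. Of its 31 measured genes, 5 rose and 26 did not pass, and 10 rose when adjusted over the list alone. The 5 were Slc7a11, Mthfd2, the serine hydroxymethyltransferase Shmt2 (0.62 ± 0.10), the pseudokinase Trib3 (0.65 ± 0.11) and the glutathione-degrading enzyme Chac1 (0.57 ± 0.11). The list's centred means were 0.12 to 0.13 on the 3 truncated arrays and -0.14 to -0.11 on the full-length arrays. The heat shock and chaperone list had a median of 0.14 with no member past the test (camera adjusted p = 0.0209, adjusted p = 0.379 with an estimated correlation), with Hspd1 at 0.44 ± 0.11, Hsph1 at 0.45 ± 0.13, Cct3 at 0.36 ± 0.11 and Cct6a at 0.31 ± 0.13. It did not pass without truncated replicate 1 (adjusted p = 0.0596) or full-length replicate 3 (adjusted p = 0.0516), with a range of 0.0021 to 0.0596 over 16 alternative fits, and 0 of its 20 genes passed when adjusted over the list alone. The list of replication-dependent histones as fixed also names H1f0 and H2az1, which are not tied to replication. Its 38 measured genes had a median of 0.14 and none passed over all genes (camera adjusted p = 0.0060, adjusted p = 0.707 with an estimated correlation). When adjusted over the list alone 13 rose and 3 fell, with H2ac11 at 0.73 ± 0.18, H3c3 at 0.61 ± 0.15 and H4c3 at 0.50 ± 0.12 but H3c7 at -0.97 ± 0.22. Many genes of this list are near-identical copies that a probe may not tell apart. The mean of the histone list was 0.16, 0.11 without truncated replicate 2 (adjusted p = 0.085), 0.26 without truncated replicate 3 and 0.07 without full-length replicate 2 (adjusted p = 0.276), with adjusted p from 8.0e-05 to 0.276 over 16 alternative fits.

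**Figure D3:**
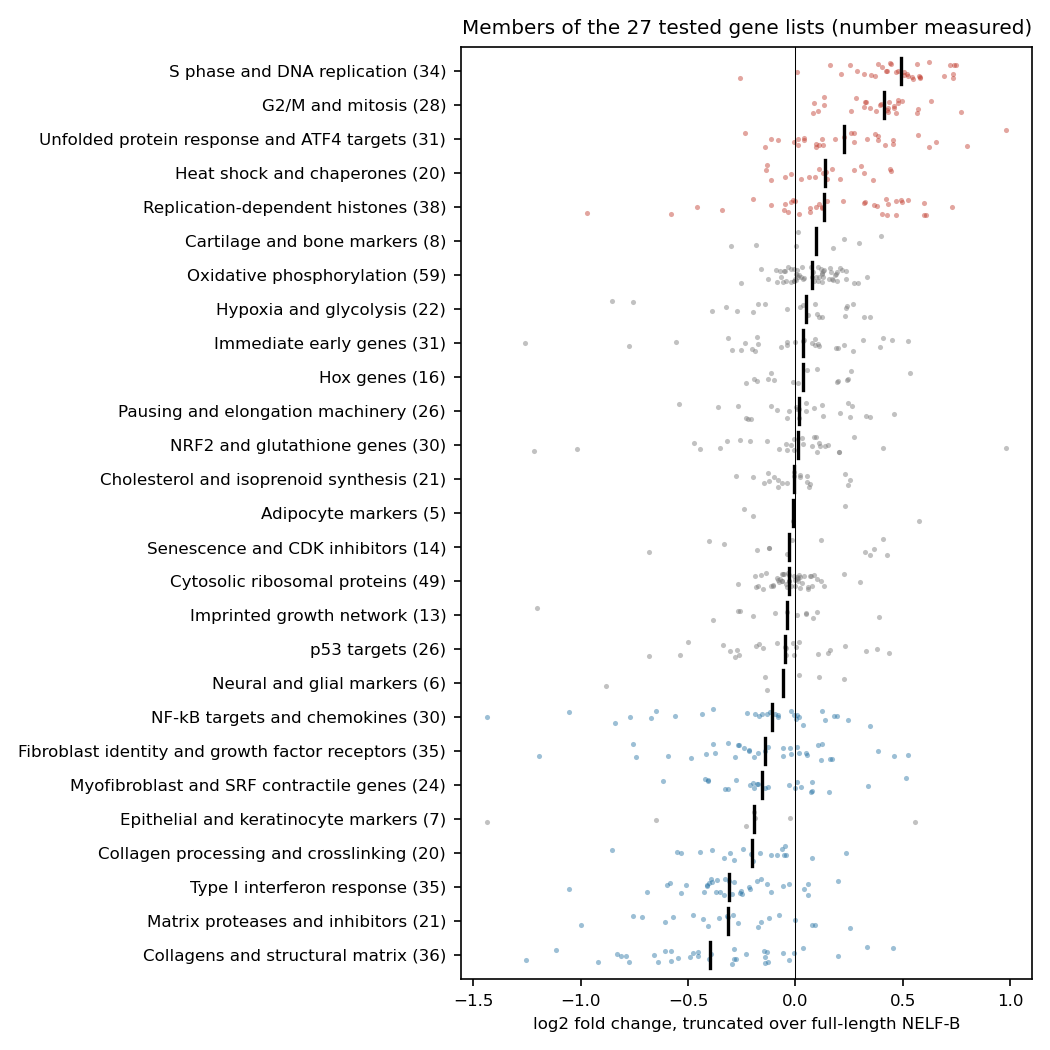
Each point is a measured member of 1 of 27 gene lists, with its log2 fold change of truncated over full-length NELF-B on the x axis, and the bar is the list's median. Red and blue mark the 5 lists shifted higher and the 7 shifted lower at a camera adjusted p under 0.05 with the preset correlation (0 of the 27 pass with an estimated correlation, 3 at an unadjusted p under 0.05), and grey the others, with medians from 0.49 for the replication list to -0.40 for the structural matrix list.

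The pausing and elongation machinery list did not pass. None of its 26 measured genes passed, the median was 0.02 and the camera adjusted p 0.844, with Mllt3 at -0.54 ± 0.16, Ncbp1 at 0.35 ± 0.13, Ints11 at 0.33 ± 0.13 and Ctr9 at -0.36 ± 0.15. Of 31 immediate early genes, Fos and the matricellular gene Ccn1 (-0.56 ± 0.11) fell and 29 did not pass, and Fosb (-0.78 ± 0.19) and Id1 (0.52 ± 0.15) stood apart in sign. A further Ccn1 probe went the other way. The median of the immediate early list was 0.04 and its mean -0.03 (camera adjusted p = 0.844). Cdkn2b, an inhibitor of CDK4 and CDK6, fell by 0.68 ± 0.10 on the log2 scale in the senescence list of 14 (median -0.03, mean 0.01, camera adjusted p = 0.993), where Hmga1 (0.41 ± 0.12), Lmnb1 (0.43 ± 0.13) and Glb1 (-0.33 ± 0.11) did not pass. No p53 target passed among 26, of which 17 had values below 0 and 9 above (median -0.05, camera adjusted p = 0.281). Sesn1 stood at -0.54 ± 0.12, Fas at -0.68 ± 0.16 and Dcxr at -0.50 ± 0.13, but Sesn2 at 0.33 ± 0.12. Of 30 NRF2 and glutathione genes, Slc7a11 rose and Gsta3 fell (-1.02 ± 0.15), and Hmox1 stood at -1.22 ± 0.31 with an adjusted p of 0.0872. The NRF2 list's median was 0.01 and its mean -0.05 (camera adjusted p = 0.837). H19 was the only 1 of 13 imprinted genes to pass, with Igf2 at -0.38 ± 0.12 and Dlk1 at 0.39 ± 0.13 (camera adjusted p = 0.208). With fry the imprinted list passed, lower (adjusted p = 0.0415), but not with an estimated correlation in camera (adjusted p = 0.379).

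No housekeeping list passed. The camera adjusted p was 0.731 for 49 cytosolic ribosomal proteins (median -0.03), 0.0886 for 59 oxidative phosphorylation genes (median 0.08), 0.879 for 21 genes of cholesterol synthesis (median -0.01) and 0.993 for 22 hypoxia and glycolysis genes (median 0.05, mean -0.04), and no member passed in any of them. The oxidative phosphorylation list passed, higher with truncated NELF-B, with no background correction (adjusted p = 0.0453), the authors' values (0.0382) and array weights (0.0210), but not with an estimated correlation (adjusted p = 0.820). It also passed without truncated replicate 3 (0.0185) and without full-length replicate 3 (0.0031). In the hypoxia list Ndrg1 stood at -0.76 ± 0.16 and Mif at 0.35 ± 0.10. None of 16 Hox genes passed (median 0.03, camera adjusted p = 0.816), with Hoxa6 at 0.53 ± 0.19.

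Markers of other cell types were mostly at background, and no list of them with at least 5 measured genes passed. Of 18 blood and erythroid markers 0 were above background in at least 3 arrays. There were 4 measured macrophage markers (median -0.04), 4 endothelial (median -0.28), 3 skeletal muscle (median 0.03) and 1 pluripotency marker, Pou5f1 at 0.10 ± 0.13, too few to test as lists. All 4 endothelial genes had values below 0, and where that list had enough probes to test it passed, lower, with every probe on its own (mean -0.29, adjusted p = 0.0109) and with no filter on dim probes (mean -0.13, adjusted p = 0.0268). With an estimated correlation neither of these passed (adjusted p = 0.250 and 0.297). The camera adjusted p was 0.128 for 7 epithelial markers, in which Lcn2 was the only one to fall and Krt19 stood at 0.56 ± 0.15, 0.612 for 6 neural and glial markers, 0.612 for 8 cartilage and bone markers and 0.844 for 5 adipocyte markers, whose median was -0.01 and mean 0.07. The epithelial list passed, lower, without full-length replicate 3 (adjusted p = 0.0365) and with fry (adjusted p = 0.0302), but not with an estimated correlation (adjusted p = 0.379). Cd14, a macrophage marker, read 10.8 ± 0.06 (SD, n = 3) with the truncated and 11.1 ± 0.05 (SD, n = 3) with the full-length form on the log2 scale and did not pass (adjusted p = 0.151). Sex-linked transcripts did not separate the forms. Xist was above background on all 6 arrays (-0.10 ± 0.13), while Eif2s3y and Kdm5d were above background on 0 arrays of either form and Uty on 1 array of each. Of 3 Ddx3y probes, 1 was above background on all arrays (-0.05 ± 0.16) and the others on 0.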

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

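The refits that keep the same probes, and those with an estimated correlation on every probe or without a filter, were chosen after seeing the data. The 44 called genes that are named kept their direction in the 264 values of the 6 settings that recompute the fold on all arrays (background, normalization and array weights). These genes were called on the same arrays, with no overlap between the forms, so a reversal was unlikely from the start. Other settings leave the fold as it was or drop an array from groups that do not overlap, and say little about direction either. The exception was the stricter detection filter, which switched the probe of C1s1 and moved its value from -1.17 to -0.56. Of 730 values over all alternatives 443 kept the call, and of 255 with 1 array left out 203 lost it. The count of 144 changed genes became 706 with no background correction, 633 with normexp without negative controls, 732 with the authors' series matrix values, 81 with median scaling, 33 with no filter on dim probes, 335 with a detection p under 0.01 on all arrays, 78 with every probe on its own, 728 with a variance trend and robust eBayes, 354 with array weights and 444 at an adjusted p under 0.1. Cyclic loess in place of quantile gave 156, of which 65.4% were lower. The share that was lower was 54.8%, 52.2%, 81.8%, 57.0%, 74.4%, 52.9% and 58.2% with normexp, the authors' values, no filter, the stricter filter, every probe, the trend and the weights. With 1 array left out the count ran from 0 to 304, and where it was 0 in limma, 1178 to 1543 genes had an unadjusted p under 0.05. Fewer arrays account for part of these losses by construction, but leaving out truncated replicate 3 raised the count. A left-out array can change which probe stands for a gene, as it did for Xrcc2 without truncated replicate 1 (0.41, 0.68 on the same probe) and C1s1 without full-length replicate 1 (-0.53, -1.16 on the same probe) and 3 (-0.68, -1.19 on the same probe). With the same probes kept, the count was 0, 9 and 276 without truncated replicates 1, 2 and 3, and 0, 0 and 6 without full-length replicates 1, 2 and 3. In those 3 refits with 0, 1184, 1439 and 1548 genes had an unadjusted p under 0.05. On the same probe, 52 of 264 values of the named called genes kept the call and 0 moved by over 1.5 times. The count of 29 genes changed at least 2-fold became 7 with no background correction, 10 with normexp, 5 with the authors' values and 14 with no filter, and ran from 0 to 45 with 1 array left out. Both kinds of value without background subtraction shrink the folds of dim genes by construction, and for the other settings the cause was not tested. With the replicate block 33 genes were called, 3 higher and 30 lower (90.9% lower), 31 of them among the 144, and 11 lists passed. Deviations from group means of same-numbered arrays correlated across genes at 0.03, -0.16 and -0.14. Truncated 3 with full-length 2 gave 0.18, and 2 with 3 gave 0.14. Deviations sum to 0 per form, so pairing stays open. The Nelfb log2 fold change stayed between 0.15 and 0.37 and never passed (adjusted p 0.0952 to 0.409). The share of genes shown to differ by less than 2-fold stayed between 94.8% and 99.8%. The number of lists past the threshold was 9 to 13 in every refit with the preset correlation and 10 with fry, in which 8 of the 12 passed and the heat shock, interferon, collagen processing and histone lists did not, but 0 of 27 with an estimated correlation in camera, where 3 had an unadjusted p under 0.05. With that correlation, 0 of 29 lists passed with every probe on its own and 0 of 33 with no filter (5 and 6 at an unadjusted p under 0.05). The replication, mitosis, structural matrix, collagen processing, matrix protease, interferon, NF-kB and ATF4 lists kept call and direction in all 16 refits with the preset correlation (the variance trend cannot change camera and is left out). Of the probes, 46.4% to 48.7% were above background per array, which limits what dim genes can show. Fitting the chip as a block was not run.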

Other observations

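The tests of normalization and of macrophage content below were chosen only after the result was seen. Some called genes outside the fixed lists are given here as single values. They were chosen after their values were seen and stand for no gene group. Transcripts lower with truncated NELF-B included Sfrp2, a secreted frizzled-related protein (-1.10 ± 0.13, SE, limma), Dkk3 (-0.78 ± 0.11), Igfbp4 (-0.56 ± 0.11), the glypican Gpc3 (-1.14 ± 0.15) and Tgfb2 (-0.80 ± 0.12). Those of haptoglobin (Hp) stood at -1.02 ± 0.14, ceruloplasmin (Cp) at -0.94 ± 0.18 and angiotensinogen (Agt) at -0.78 ± 0.11. Asf1b, a histone chaperone, was higher (0.71 ± 0.14), and so was Hirip3 (0.67 ± 0.13).

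Nucleolar ribosome assembly genes, a list of 68 written after the called genes were seen but before its own values were, leaned higher with truncated NELF-B. Of 53 measured, 47 had values above 0, with a median log2 fold change of 0.29, and 14 rose when adjusted over the list alone. Genes already called or named were kept out of the list, so its count of 0 called over all genes was fixed in advance. Rrp12 stood at 0.53 ± 0.13 (adjusted p = 0.0773) and Ncl, nucleolin, at 0.43 ± 0.11 (adjusted p = 0.0957). Camera gave p = 1.0e-10 with the preset correlation and p = 0.0668 with an estimated one, so the hypothesis that this list rose with the replication genes stays open. A list of 49 growth arrest and quiescence genes, 6 of them also in the fixed lists, was predicted to be lower. Of 35 measured, 24 had values below 0, with a median of -0.19. Genes already called or named were kept out here too, so 0 called was again fixed in advance. Camera gave p = 0.0242 with the preset and p = 0.329 with an estimated correlation, and Cited2 (0.44 ± 0.12) and Ccnd1 (0.43 ± 0.13) stood the other way, so this too stays open.

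The replication list shifted higher and the structural matrix list lower with the preset correlation, though neither passed with an estimated one (adjusted p = 0.287 each), and 29 of 34 and 29 of 36 genes did not pass. Normalization between arrays is argued against as the whole cause, since with median scaling or cyclic loess in place of quantile the smallest mean of either list was 0.872 of its main size, with the same sign. The medians of 0.49 and -0.40 lay outside the central 95% of 10000 random lists matched on signal, which ran from -0.08 to 0.09 and from -0.07 to 0.08. Random lists of like signal thus did not shift as far in the normalized values. This does not decide on a trend with signal intensity. Quantile normalization gives every array the same distribution, so medians of random lists lie near no change by construction. Both lists were also taken up after their medians were seen, and random genes need not vary together as list members do. That samples of 1 form differed among themselves, in growth state or otherwise, may account for part of the shifts of these lists. The difference between truncated replicates 1 and 3 correlated in size at 0.346 with the difference between the forms on the other arrays. Among full-length pairs the size was at most 0.0495, and genes are not independent replicates. Truncated replicates 1 and 3 also differed in the share of probes above background (46.4% and 48.7%). Full-length replicate 3, at 47.0%, nevertheless had the lowest replication list mean (-0.33), and what this axis reflects was not tested. Such a difference among samples cannot be told apart from an effect of the NELF-B form, since each form has only its own samples. A biological effect of the form stays open, untested.

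The NF-kB and interferon lists shifted lower with the preset correlation, though not with an estimated one (adjusted p = 0.366 and 0.379), and 27 of 30 and 34 of 35 genes did not pass. Whether fewer macrophages in the truncated samples account for this could not be read from the fold changes of their markers. The mean log2 fold change of the 4 macrophage markers above background was -0.071 ± 0.085 (SE), against a level of -0.54, set at 0.5 of the mean of the 4 called genes of the NF-kB and interferon lists (-1.08). Only 1 of the 4, Cd14 (-0.30 ± 0.10, not called), was bright enough to show such a fall above background, so the mean decides nothing. Of the 18 markers listed, 11 were above background on 0 arrays, among them Lyz2, Tyrobp, C1qa and C1qb, which are abundant in macrophages. These 11 argue against macrophages as a large part of the samples of either form. The called genes C3 and Bst2 read 12.1 and 10.4 on the log2 scale with the full-length form. Cd14 was bright and lower, but with the 11 other markers at background its signal need not come from macrophages. A small macrophage content stays open.

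The 6 arrays allow 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 144 changed genes, 29 of them at least 2-fold, and 12 gene lists, and 1 of the 10 splits, the real one, gave as many in each case. The highest of the other splits gave 0 genes, 0 genes at least 2-fold and 9 lists (limma and camera). Each other split mixes the forms, so a difference between them would widen the spread within its groups and lower its gene count. Its lists can also keep part of that difference. These counts are thus no measure of what chance gives. The split with 9 lists set truncated replicates 1 and 2 with full-length replicate 1 against the rest and had 480 genes at an unadjusted p under 0.05, where the real split had 1808 and the highest other split 809.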
